A study of Homo sapiens with 272 samples.

How the data were processed

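Enhanced crosslinking and immunoprecipitation (eCLIP) crosslinks proteins to RNA in cells with ultraviolet light, precipitates 1 protein with its RNA and sequences the RNA fragments. Each precipitate (IP) is paired with a size-matched input, a library from the same lysate that was cut from the same size range without enrichment for the protein. The labels describe 272 libraries, in 68 experiments of 2 IP and 2 input libraries each. They come from K562, a human erythroleukaemia line, and HepG2, a human liver carcinoma line. Tables of reproducible enriched windows were analysed for 67 experiments, and the experiment on RPS10 in K562 was not analysed here. Experiments are named by protein, cell line and the experiment number in the labels. The K562 experiment labelled TDP43 and the HepG2 experiment labelled TARDBP were treated as 1 protein, TARDBP, since TDP-43 is the product of that gene.

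Reads were aligned with STAR to the human genome build hg38, per the submitters' processing notes. The version of STAR, the window caller and the annotation release are not given in the sources used here. Per the file headers and values, each table lists windows of at most 100 nt within annotated transcripts that were called in both replicates. Each window carries a feature type and 1 or more gene names. The IP and input counts in the deposited tables are whole reads per window, each summed by the authors over 2 libraries. The enrichment was deposited by the authors as a log2 odds ratio of IP over input, given as the lower replicate, the mean and the higher replicate. The mean equalled the midpoint of both replicates within 0.001 in all 1173449 listed windows. The authors deposited the highest and the lowest p-value and q-value over the replicates, and the highest q was under 0.2 in every window. The G+C content of a window was deposited as a fraction. Because the tables join both replicates, no value per library was available, and the error printed beside a window is the range from the lower to the higher replicate.

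The tables list only windows that passed, so their summed reads are not the depth of a library. The IP reads within listed windows ranged from 22773 to 7834197 per experiment, with a median of 961733. Over all listed windows the median was 34 IP reads and 2 input reads, and 20.8% of the windows had 0 input reads. Odds ratios against 0 input reads are bounded by counting error, and they depend on how the authors treated zeros, which is not given in the sources used here. Low depth also shortens a list. Experiments with few windows were therefore kept out of shares per protein below a minimum of 50 windows, which removed PARP in HepG2 with 38 windows.

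Windows were matched between experiments by chromosome, start, end and strand, with coordinates printed 1-based on hg38. Feature types were grouped as coding sequence, 5' UTR, 3' UTR, splice-site regions (types labelled adjacent or proximal to a 5' or 3' splice site, or to both), other intronic windows (called deep introns here) and exons of small RNA genes. The distances behind "adjacent" and "proximal" are not given in the sources used here. No separate feature type for tRNA genes was present in the tables, so exons of small RNA genes, which include mitochondrial rRNA, stood in for them. Of the 13938 gene names in the tables, 12705 matched a symbol of the RefSeq gene table for GRCh38.p14, and 1183 were Ensembl identifiers. That table was used for names only. Windows that overlap several genes carry all their names (3.13% of the listed windows) and were counted for each.

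The protein was the unit of replication. Before the data were examined, 51 proteins were placed by textbook function into 9 classes and a remainder, and 1 feature was fixed for each class. A protein's value was the mean over its experiments of the share of its windows in that feature. Class members were compared with all other proteins by a two-sided exact permutation test of the rank sum, with Benjamini-Hochberg adjustment over the 9 tests and a threshold of 0.05. Overlap between 2 experiments was the log2 odds ratio of shared windows, with 0.5 added to each cell and all 656912 distinct windows as the universe. The pairing of proteins across the lines, the class labels and the pairing of proteins with their genes were permuted 100000 times, one-sided for more overlap, so that 1e-05 is the smallest p these tests can give. Paired differences between the lines were tested by an exact two-sided sign-flip permutation test. The share of a fixed gene list with a window, minus the share of all named genes with a window, was compared by the exact rank-sum permutation test, adjusted over 13 lists. Marker genes of each line were compared in the same way, with experiments rather than proteins as the unit and without pairing. P-values refer to the spread between proteins or experiments, not between libraries.

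The rule for named genes was also fixed before the data were examined. It took the 5 genes with the largest difference between the share of class members and of other proteins with a window. It also took up to 3 genes with the highest mean log2 odds ratio at a q of at most 0.05 in an experiment described singly. The remaining parts were the gene of the highest window shared between the lines, each protein's own gene, and members of the fixed lists. XIST and Y-linked genes were left out. The pairs of proteins named for their overlap, and the counts of small RNA families, were chosen after the values were seen. The pattern that selects snRNA genes was corrected after the gene names had been seen, because the first form took in other genes, and before any list was tested. Fixed lists covered spliceosomal snRNAs, snoRNAs and scaRNAs, 7SK, 7SL, RNase P, RNase MRP and telomerase RNAs, nuclear lncRNAs, ribosomal protein mRNAs, translation factor mRNAs, histone mRNAs, SR protein mRNAs, hnRNP mRNAs, AU-rich immediate early mRNAs, microRNA host genes, mitochondrial RNAs and mRNAs of Polycomb, SET1 and HUSH subunits. Markers of K562, of HepG2 and of fibroblasts, lymphocytes and endothelium were fixed too.

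The class, overlap, own-gene and intron-share tests were tried on simulated data with known answers, the chromatin class with 9 of 51 proteins where the test itself used 8 of 50. The list and marker tests, Dixon's ratios and the permutation of classes over the shared sets were not simulated. With no effect, the class tests made calls in 1.5% to 6% of 200 simulations. With class members raised by 2 SD, they made calls in 80.5% to 100%. The simulated calls used the unadjusted p of each class alone, without the Benjamini-Hochberg step over the 9 tests. The rates are therefore those of a more lenient test, and the power of the adjusted class tests was not simulated. Overlap was planted in 20% of each simulated list, drawn from 20000 windows, and own-gene binding in the simulated proteins. Both were recovered at p = 0.0001 (permutation tests), the smallest that simulation's permutations could give. The simulated lists were of nearly equal length, whereas the real lists ran from 38 to 141887 windows. Alternatives were a highest q of at most 0.01, a lower-replicate log2 odds ratio of at least 1, genes in place of windows, minima of 200 windows or none, K562 alone, other overlap measures and universes, exonic windows alone, and leaving out each protein or class. Alternatives added after seeing the data left out windows listed in 15 or more experiments, left out windows of the shared sets described at the end, left out PRPF39 in K562 with DEK experiment 4146, used only splice-site adjacent windows, and counted an overlap of 1 nt as shared. Tests of sequence motifs were planned and not run, because no genome sequence was used here. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.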

Results

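The series mapped the RNA targets of 51 proteins by eCLIP in 45 experiments on K562 cells and 22 on HepG2 cells. Each experiment joined 2 biological replicate IP libraries with their size-matched inputs, and 14 proteins were studied in both lines. The tables list 1173449 window calls at 656912 distinct windows in 13938 genes. K562 experiments listed 524069 distinct windows and HepG2 experiments 212462, with 79619 in common. An experiment listed a median of 8709 windows, from 38 for PARP in HepG2 to 141887 for EED in K562, and 65.5% of the windows appeared in 1 experiment only. In the authors' deposited tables the median log2 odds ratio of an experiment ranged from 2.15 (EEF2 in K562) to 7.26 (PARP in HepG2), and the typical gap between replicates was 0.77.

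Intronic windows away from splice sites made up 43.5% of all calls, coding sequence 26.9%, splice-site regions 10.2%, 3' UTRs 9.61%, 5' UTRs 3.87% and exons of small RNA genes 0.302%. The proteins divided these features unevenly. EED, a subunit of Polycomb repressive complex 2, had 91.5% of its windows in deep introns, and FMRP, the protein lost in fragile X syndrome, had 93.3% in coding sequence. AGO2, the microRNA effector, had 45.2% in 3' UTRs, and the translation initiation subunit EIF3A had 49.4% in 5' UTRs. PRPF39, a U1 snRNP-associated splicing factor, had 32.4% of its windows at splice sites in HepG2 experiment 4114. The nucleolar protein NPM1 had 25.2% in exons of small RNA genes. The plot of class shares shows each protein beside its class.

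**Figure D1:**
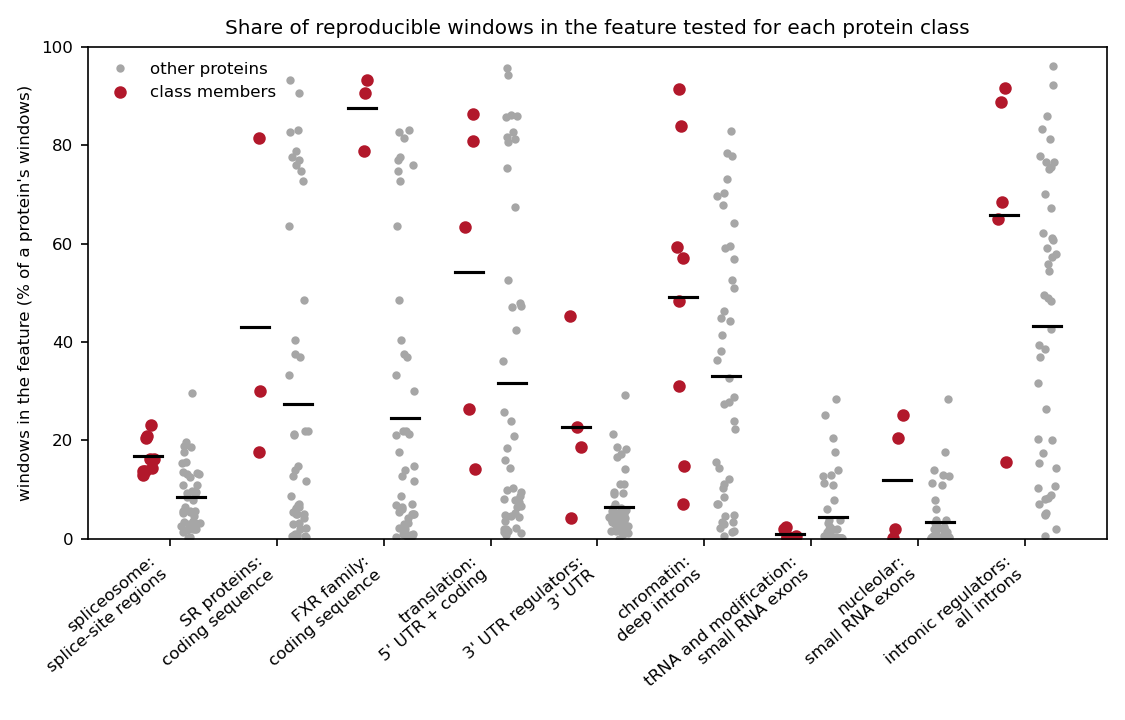
Share of a protein's windows (percent, vertical axis) in the feature tested for each of 9 protein classes (horizontal axis). Red points are class members, grey points the other proteins with at least 50 windows, and black lines the means. The 9 spliceosomal proteins lie between 13.01% and 23.1% in splice-site regions against a mean of 8.42% for the others, and the 3 FXR proteins between 78.8% and 93.3% in coding sequence.

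The first question was whether proteins of 1 function bind the part of the transcript where they act. Spliceosomal proteins had more of their windows at or near splice sites than other proteins, at 16.9% ± 3.72 (SD, n = 9) against 8.42% ± 6.56 (n = 41). The difference was 8.44 points (adjusted p = 0.0014, exact permutation test), and all 9 members lay above the mean of the others. SNRNP200, the U5 snRNP helicase, had the highest share of the class at 23.1%, followed by PRPF39 (21.0%) and the Sm core protein SNRPD3 (20.5%), and MFAP1 of the B complex had the lowest at 13.01%. Means over experiments hid differences between the lines: PRPF39 had 32.4% and 26.5% in HepG2 but 4.07% in K562, and SF3A1 29.2% in HepG2 but 3.09% in K562, both K562 values below the mean of the other proteins. The members differed in the side of the intron. SF3A1, a U2 snRNP subunit, had 22.3% of its HepG2 windows adjacent to 3' splice sites and 1.07% adjacent to 5' splice sites. SNRPC, the U1 snRNP subunit U1-C, had 6.64% adjacent to 5' splice sites and 1.95% adjacent to 3' splice sites in K562. TIAL1, the U-rich element binding protein TIAR placed in another class, had 29.5% of its windows at splice sites in its only experiment, in K562. That exceeded the mean over experiments of every spliceosomal protein, though PRPF39 reached 32.4% in HepG2 experiment 4114. The 5' adjacent type made up 17.0% of all TIAL1 windows. The SF3A1 share in 3' adjacent windows was 0.515% in K562.

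Of the 5 genes with the largest difference for the spliceosomal class, the U2 gene RNU2-2P had a window in 8 of 9 spliceosomal proteins and 6 of 41 others, and WDR74, which overlaps it, in 9 of 9 and 14 of 41. RNU2-1 had one in 7 of 9 against 3 of 41, LINC00910 in 8 of 9 against 9 of 41, and SLC25A43, which contains the U1 copy RNU1-67P, in 7 of 9 against 6 of 41. The RNU2-2P window on chromosome 11 (62841714 to 62841809), listed in 18 experiments, had 14032 IP reads against 3297 input reads in SNRNP200 HepG2 in the authors' deposited table, with a log2 odds ratio of 5.46 (4.84 to 6.09 over the replicates). LINC00910 on chromosome 17 (43387248 to 43387346) reached 8.65 (7.05 to 10.25) in SNRPD3 HepG2 in the authors' deposited table. Single genes were named by the size of their difference and had no test of their own. The class difference was 5.35 points with K562 experiments only (adjusted p = 0.209, exact permutation test) and 5.60 with each gene counted once per feature (adjusted p = 0.0913, exact permutation test). It also missed the threshold with a highest q of at most 0.01, the last of 3 alternatives that changed the call.

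Counts over the snRNA families differed between experiments, with the limits that reads cannot be placed with certainty among the near-identical copies and that no test was run. SNRPC and SNRPD3 in K562 each had windows in 29 of 35 listed U1 genes and copies, the most of all experiments, where the median experiment had 0. ELAC2 (17) and EIF3A (15), which are not spliceosomal, ranked next after SNRPD3 (24) and SNRPC (18) in HepG2. PRPF39 had 9 in K562 and 0 in both HepG2 experiments, and the U2 protein SNRPA1 had 8 of the U1 family and 4 of the U2 family. SNRNP200 in HepG2 had the most U4 (7 of 10), U5 (9 of 10) and U6 (42 of 54) genes and copies, and SNRNP200 in K562 came second for U4 (5) and U5 (8). SNRPD3 in K562 led for U2 with 8 of 13, before SNRNP200 in HepG2 with 7. MFAP1 was second for U6 with 13, and in the authors' deposited table its highest window was RNU6-19P on chromosome 15 (65553134 to 65553187), with 822 IP reads against 1 and a log2 odds ratio of 10.26 (9.85 to 10.67). No other experiment listed that window.

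The 3 proteins of the fragile X family bound coding sequence. Their share was 87.6% ± 7.73 (SD, n = 3) against 24.6% ± 28.3 (n = 47), a difference of 63.0 points (adjusted p = 0.0032, exact permutation test), with 93.3% for FMRP, 90.6% for FXR1 and 78.8% for FXR2. FXR2 had 67.4% in K562 and 90.1% in HepG2. The share was not unique to the family: EXOSC10 of the nuclear exosome (83.2%), the SET1 subunit CXXC1 (82.8%), SRSF1 (81.6%), DDX43 (77.6%) and CNOT2 (77.1%) also bound mainly coding sequence. Of the EXOSC10 windows, 93.4% were also listed for DDX43. In K562, FMRP and FXR1 shared 5992 windows (48.8% of the smaller list), FXR1 and FXR2 6998 (57.0%), and FMRP and FXR2 6313 (49.9%). PRKDC, the catalytic subunit of DNA-dependent protein kinase, held the highest FMRP window found in fewer than 12 experiments, on chromosome 8 (47788906 to 47788977), with a log2 odds ratio of 8.70 (8.62 to 8.78) in the authors' deposited table. The limit of 12 experiments was not part of the fixed rule for named genes. Over all FMRP windows the highest mean log2 odds ratio was 10.77. KDM5C, MCM3AP, RNF213 and PPP6R1 had coding windows that also carry the names of the overlapping genes MIR6895, ENSG00000239415, ENSG00000280248 and MIR6803. Each of these overlapping genes, all chosen by the fixed rule, had a window in 3 of 3 family members and 4 of 47 others. The pseudogene TCAF1P1 had one in 3 of 3 against 2 of 47. With a highest q of at most 0.01 the difference turned negative for TCAF1P1 and MIR6803.

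Regulators of the 3' UTR had 22.7% ± 17.0 (SD, n = 4) of their windows there against 6.44% ± 6.37 (n = 46), a difference of 16.2 points (adjusted p = 0.0497, exact permutation test). AGO2 had 45.2%, TIAL1 22.7% and the AU-rich element binding protein ELAVL1 18.6%, while CNOT2, a subunit of the CCR4-NOT deadenylase, had 4.14%. CNOT2 had 77.1% in coding sequence and ELAVL1 64.3% in deep introns. SMG8, which acts in nonsense-mediated decay, had a window in 4 of 4 class members and 4 of 46 others, and CAPN10, SC5D and PCYOX1 in 4 of 4 and 5 of 46. With a highest q of at most 0.01 the difference turned negative for CAPN10 and PCYOX1. The SMG8 window in the 3' UTR on chromosome 17 (59215082 to 59215160) had 77 IP reads against 0 in TIAL1 in the authors' deposited table, with a log2 odds ratio of 5.90 (5.74 to 6.05). The highest windows of AGO2 lay in NFYC, at the MIR425 and MIR191 genes within DALRD3, and in HOXB3, with log2 odds ratios of 13.44, 12.39 and 12.14 in the authors' deposited table. AGO2 also had windows in the most microRNA genes of all experiments, 98 of 226. It had windows in 64.8% of all named genes as well, the most of all experiments and a larger share than of the microRNA genes. The call for 3' UTRs was close to the threshold: without AGO2 the difference was 8.70 points (adjusted p = 0.173, exact permutation test), without ELAVL1 17.6 (adjusted p = 0.167, exact permutation test) and without TIAL1 16.2 (adjusted p = 0.182, exact permutation test).

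The other 6 classes did not pass the test. Translation proteins had 54.2% ± 32.4 (SD, n = 5) in 5' UTRs and coding sequence against 31.7% ± 33.0 (n = 45; adjusted p = 0.180, exact permutation test). EIF3A had 86.4%, the ribosomal protein RPS6 80.8%, the cap-binding protein EIF4E 63.4%, EEF2 26.4% and EIF6 14.1%. EIF3A and EIF4E had the highest 5' UTR shares of all proteins, 49.4% and 42.1%. EIF3A had windows in 53 of 55 histone genes. In the authors' deposited table its windows in the 5' UTRs of H4C11 (chromosome 6, 27824092 to 27824124) and H4C5 (chromosome 6, 26204610 to 26204644) had log2 odds ratios of 8.72 (8.63 to 8.81) and 8.47 (8.18 to 8.75). H4C5 had a window in 5 of 5 translation proteins and 18 of 45 others, FMC1 in 5 of 5 and 17 of 45, and H4C11, SNORD4A and ENSG00000281010 each in 4 of 5 and 10 of 45.

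Intronic regulators had 65.9% ± 30.5 (SD, n = 5) of their windows in all introns against 43.3% ± 29.3 (n = 45; adjusted p = 0.180, exact permutation test). The paraspeckle protein NONO had 91.7%, TARDBP 88.7%, HNRNPK 68.5% and the splicing regulator MBNL1 65.1%. FUBP1, with only 77 windows, had 15.6%, and without it the difference was 35.2 points (adjusted p = 0.0405, exact permutation test). METTL21A, LYRM4, PLEKHF2, TPT1-AS1 and KCNIP2 each had a window in 4 of 5 class members and in 6 to 9 of 45 others. The KCNIP2 window near a 5' splice site on chromosome 10 (101830772 to 101830871) had 506 IP reads against 0 in TDP43 K562 in the authors' deposited table, with a log2 odds ratio of 8.87 (8.51 to 9.24).

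Chromatin proteins had 49.1% ± 30.4 (SD, n = 8) in deep introns against 33.1% ± 26.6 (n = 42; adjusted p = 0.185, exact permutation test). EED had 91.5% and RYBP, of Polycomb repressive complex 1, 84.0%, whereas CXXC1 had 7.01% and DEK 14.7%. EED and RYBP, both Polycomb subunits, shared 286 windows (log2 odds ratio of overlap -3.04, against a median of -0.69 for either of them with the other K562 experiments). ENSG00000289474 had the largest difference, with a window in 6 of 8 members and 12 of 42 others. The mitochondrial MT-CO2 had one in 8 of 8 against 24 of 42, the mitochondrial rRNA MT-RNR2 in 7 of 8 against 21 of 42, FRMD4B in 5 of 8 against 11 of 42 and NSMF in 6 of 8 against 17 of 42. With a highest q of at most 0.01 the difference turned negative for FRMD4B and NSMF.

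SR proteins had 43.1% ± 33.9 (SD, n = 3) in coding sequence against 27.4% ± 31.3 (n = 47; adjusted p = 0.262, exact permutation test). SRSF1 had 81.6% of 66821 windows, SRSF5 30.02% of 423 and SRSF9 17.7% of 674, with a further 29.7% of the SRSF9 windows in 5' UTRs. Without SRSF1 the sign turned to -3.57 points. TRAF4, MEIOB and MT-ND3 had a window in 3 of 3 SR proteins and in 20, 17 and 18 of 47 others, and CCDC85B and NAP1L4P1 in 2 of 3 and 4 of 47. The difference turned negative for MEIOB, TRAF4 and CCDC85B with a highest q of at most 0.01, and for MT-ND3 without windows listed in 15 or more experiments. Nucleolar proteins had 11.9% ± 12.7 (SD, n = 4) in exons of small RNA genes against 3.29% ± 5.87 (n = 46; adjusted p = 0.210, exact permutation test). NPM1 (25.2%) and nucleolin, NCL (20.4%), stood above DDX47 (1.88%) and EXOSC10 (0.0938%). SNORD3A, a gene for U3, the snoRNA of early rRNA processing, had a window in 4 of 4 nucleolar proteins and 14 of 46 others, and its near-identical copies SNORD3D and SNORD3B-2 in 4 of 4 and 3 of 4. In the authors' deposited table the SNORD3A window on chromosome 17 (19188016 to 19188114) had 108244 IP reads against 37802 input reads in NPM1, with a log2 odds ratio of 6.81 (6.73 to 6.89).

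Proteins that act on tRNA or modify RNA had 0.956% ± 0.919 (SD, n = 6) of their windows in exons of small RNA genes against 4.39% ± 7.22 (n = 44, adjusted p = 0.919, exact permutation test). The medians lay the other way, at 0.511% and 0.442%. Exons of small RNA genes only stood in for tRNA genes, so these shares cannot show whether the proteins bound tRNA. Their highest share was 2.26%, for the glycyl-tRNA synthetase GARS. PHKG2 and LINC00324 had a window in 6 of 6 members and in 18 and 19 of 44 others, RNF215 and OSBP2 in 5 of 6 and 12 of 44, and SNORD10 in 4 of 6 and 4 of 44. In the authors' deposited table the LINC00324 window on chromosome 17 (8222784 to 8222881) had 4953 IP reads against 45 in NSUN2 HepG2, with a log2 odds ratio of 8.04 (6.71 to 9.37).

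The second question was whether a protein keeps its windows between the lines. A protein's windows in 1 line overlapped those of the same protein in the other line more than those of other proteins. The mean percentile of the same protein was 86.7 (n = 14) against 49.3 with permuted pairing (p = 1e-05, permutation test, the smallest it can give). ELAVL1, NONO and TARDBP ranked first in both directions. TARDBP shared 8970 windows, 76.0% of its shorter list, ELAVL1 11853 (45.5%), NONO 7808 (43.0%), FXR2 3565 (39.98%) and SNRPC 4990 (38.8%). PRPF39 was the exception: its 172 windows in K562 included none of the 16498 or 27352 windows of its HepG2 experiments.

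**Figure D2:**
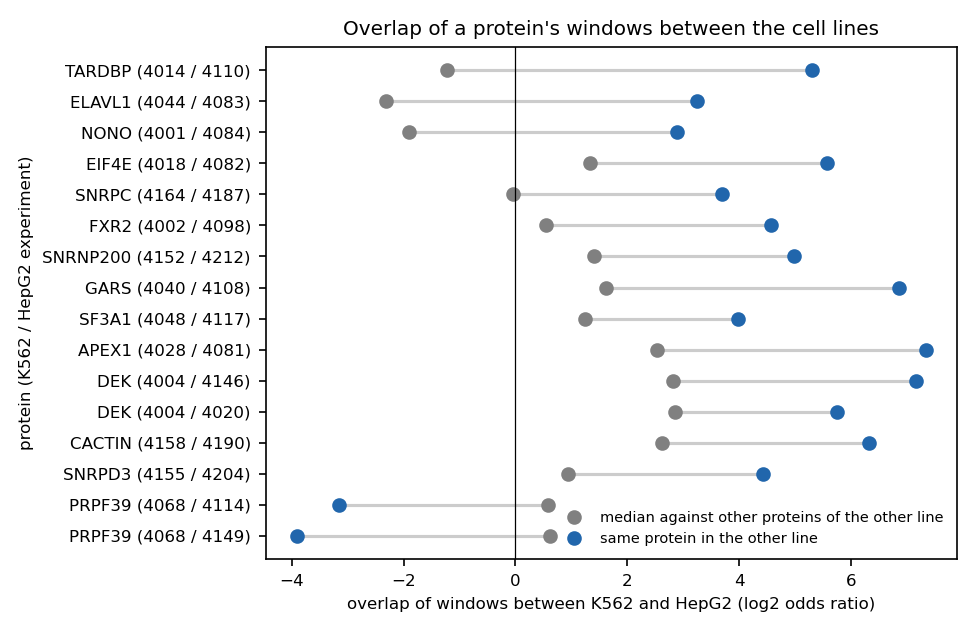
Overlap of windows between K562 and HepG2 (log2 odds ratio, horizontal axis) for each of 16 pairs of experiments of 1 protein (vertical axis, with the K562 and HepG2 experiment numbers). Blue points give the overlap with the same protein and grey points the median overlap with other proteins of the other line. The same protein lies to the right in all pairs but those of PRPF39, at -3.15 and -3.91.

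The strongest shared windows were specific to few experiments for some proteins and common to many for others. ELAVL1 bound the 3' UTR of ICAM1, a cell adhesion receptor, on chromosome 19 (10286521 to 10286615), at log2 odds ratios of 8.13 (7.90 to 8.37) in K562 and 7.497 (6.28 to 8.71) in HepG2 in the authors' deposited tables. TARDBP bound an mRNA exon of GAK on chromosome 4 (887265 to 887363) at 10.46 (10.33 to 10.59) and 11.58 (11.22 to 11.95) in the authors' deposited tables. SNRPC bound a window adjacent to a 5' splice site of TLK1 on chromosome 2 (170996553 to 170996652) at 7.67 (6.33 to 9.01) and 6.94 (6.18 to 7.70) in the authors' deposited tables. EIF4E bound the 5' UTR of MZT2B on chromosome 2 (130182224 to 130182282) at 4.63 (4.16 to 5.10) in K562 and 6.77 (6.38 to 7.17) in HepG2 in the authors' deposited tables. FXR2 bound coding sequence of PRKDC on chromosome 8 (47935009 to 47935058) at 6.67 (6.27 to 7.06) and 6.36 (6.01 to 6.70) in the authors' deposited tables. For SF3A1 the gene was TNKS, for GARS SEC24A, for NONO ARID3A, for SNRNP200 EVI5 and for SNRPD3 TMEM184B. The TNKS window was listed in 12 experiments and the ARID3A window in 10, and those of the other proteins above in 2 to 6. APEX1, CACTIN and DEK had common windows as their highest shared ones, in MIR17HG (listed in 17 experiments), ENSG00000230021 (37) and TRRAP with MIR3609 (35).

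The share of windows in introns showed no common shift between the lines. It was higher in HepG2 by 6.52 points ± 27.8 (SD, n = 14), in 9 of 14 proteins (p = 0.390, exact sign-flip permutation test). Single proteins moved both ways: PRPF39 gained 48.6 points to reach 73.6% in HepG2, GARS had 35.5% in K562 and 76.3% in HepG2, SF3A1 14.6% and 48.8%, and APEX1, a DNA repair endonuclease, 78.3% and 20.9%. The APEX1 list in K562 held only 60 windows. Differences in the other 6 features had adjusted p-values of 0.587 to 0.761 (exact sign-flip permutation tests).

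DEK and PRPF39 were each studied in a pair of HepG2 experiments. The PRPF39 experiments 4114 and 4149 shared 10758 windows, 65.2% of the shorter list (Jaccard index 0.325), and overlapped more with each other (log2 odds ratio 6.14) than either did with any other HepG2 experiment (highest 3.84). The DEK experiments 4020 and 4146 shared 494 windows, 47.2% of the shorter list (Jaccard index 0.103, log2 odds ratio 7.29). Experiment 4146 overlapped more with other proteins, up to 10.73 for SNRPA1. Coding sequence held 62.3% of the windows of experiment 4020 (95% Wilson interval 60.9% to 63.8%) and 13.2% of those of 4146 (11.3% to 15.4%). Exons of small RNA genes held 3.16% (2.68% to 3.73%) and 24.5% (22.0% to 27.2%). These intervals cover counting error only.

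The third question was whether proteins of 1 class share windows within K562. Pairs within a class overlapped more (mean log2 odds ratio 3.17 over 87 pairs) than pairs of different classes (1.98), a difference of 1.19 (p = 0.00097, permutation test, n = 45 proteins). Translation proteins had the highest mean within their class (5.95 against 3.41 to other proteins), followed by the FXR family (5.93 against 1.35) and nucleolar proteins (4.86 against 2.90). Proteins of the tRNA and modification class overlapped no more with each other (1.97) than with others (2.26). Single classes were not tested. NCL and NPM1 shared 482 windows (48.7% of the shorter list), SNRPC and SNRPD3 10150 (71.0%), and EIF3A and EIF4E 2393 (58.0%). ELAVL1 and TIAL1 shared 10570 windows, 18.3% of the shorter list. Short lists had high odds ratios with most others, as the map shows for FUBP1, APEX1 and EEF2.

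**Figure D3:**
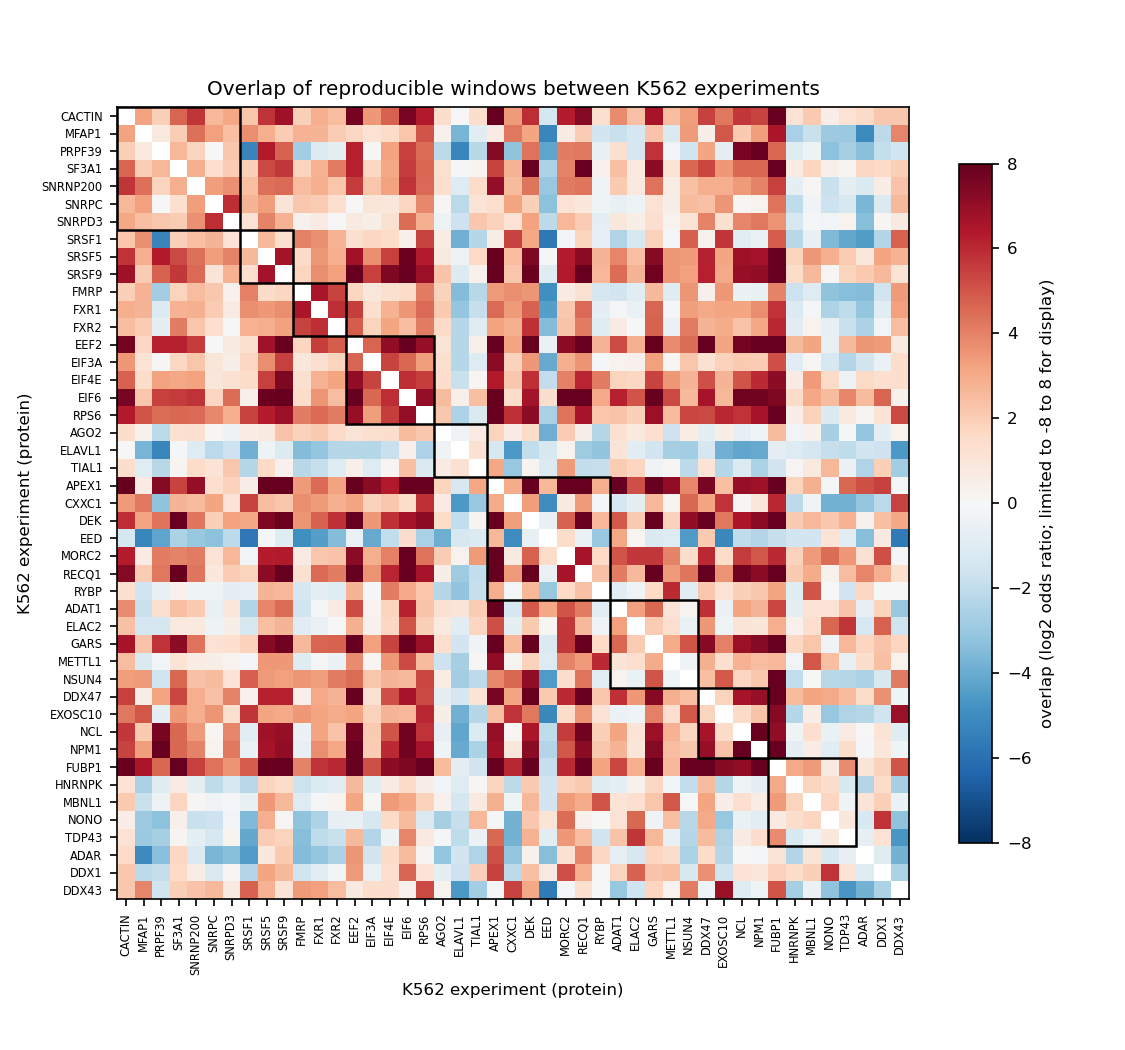
Overlap of windows (log2 odds ratio, colour, limited to the range from -8 to 8) between the 45 K562 experiments, on both axes, ordered by class, with each class framed in black and the diagonal left blank. The frames of the FXR family and the translation proteins hold mean values of 5.93 and 5.95.

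The fourth question was whether the proteins bind the RNA of their own gene. A window in the own gene was found for 26 of 51 proteins, against 20.4 ± 2.37 (SD over permutations) with proteins and genes permuted (p = 0.0145, permutation test). TARDBP bound its own 3' UTR on chromosome 1 in both lines, at log2 odds ratios of 8.01 (6.95 to 9.07) in HepG2 (11023427 to 11023525) and 6.57 (6.48 to 6.66) in K562 (11023823 to 11023921) in the authors' deposited tables. ELAVL1 bound its own 3' UTR on chromosome 19 (7962301 to 7962399) at 6.90 (6.35 to 7.45) in K562, and TIAL1 its own on chromosome 10 (119580725 to 119580809) at 6.43 (5.67 to 7.19), in the authors' deposited tables. AGO2 (7.16) and FXR2 (5.40 in K562 and 2.93 in HepG2) had their highest own windows in coding sequence in the authors' deposited tables. EED (6.94) had its highest in an intron, PPP1R10 (6.39) near a 5' splice site and EIF3A (4.66) in its 5' UTR, in the authors' deposited tables. NONO, NPM1, RPS6 and SNRPD3 were among the 25 proteins with no window in their own gene. With a highest q of at most 0.01 the number was 13 (p = 0.133, permutation test).

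In the main analysis, none of 13 gene lists fixed for a class passed after adjustment. Under 6 alternatives each, the snRNA list passed in 2 and the 7SK and 7SL list in 1. Each value was the share of list genes with a window minus that of all named genes. For snRNA genes, spliceosomal proteins averaged 0.363 points, close to all named genes, and others -16.1. The difference was 16.4 points (n = 9 and 41, unadjusted p = 0.00902, adjusted p = 0.0586, exact permutation test). The 3' UTR regulators exceeded others by 17.2 points in AU-rich immediate early mRNAs (26.6 against 9.37, n = 4 and 46, unadjusted p = 0.00727, adjusted p = 0.0586, exact permutation test). Nucleolar proteins exceeded others by 25.3 points in the 7SK, 7SL, RNase P and MRP list (10.1 against -15.2, unadjusted p = 0.0166, adjusted p = 0.0718, exact permutation test). In snoRNAs and scaRNAs they exceeded others by 41.5 points (28.45 against -13.1, adjusted p = 0.182, exact permutation test). NPM1 had windows in 150 of 179 snoRNA and scaRNA genes and NCL in 100, but the chromatin protein DEK in HepG2 experiment 4146 had windows in 139. The nucleolar DDX47 had windows in 6 SNORD genes and 1 scaRNA gene, and EXOSC10 in 2 SNORD genes. Translation proteins exceeded others by 19.3 points in ribosomal protein mRNAs (adjusted p = 0.188, exact permutation test) and by 7.99 points in translation factor mRNAs (adjusted p = 0.612, exact permutation test). RPS6 had windows in 56 of 79 ribosomal protein genes and EIF4E in K562 in 69, but the spliceosomal proteins SNRNP200 and MFAP1 in K562 had windows in 75 and 76.

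The remaining lists lay close to the other proteins or below them. Intronic regulators were at 5.02 points in nuclear lncRNAs (adjusted p = 0.919, exact permutation test) and at -13.5 points in hnRNP mRNAs (adjusted p = 0.315, exact permutation test). SR proteins were at 3.45 points in SR protein mRNAs, 3' UTR regulators at -5.12 points in microRNA host genes and the tRNA class at 0.736 points in mitochondrial RNAs (adjusted p = 0.919 each, exact permutation tests). Chromatin proteins were at -1.71 points in histone mRNAs (adjusted p = 0.919, exact permutation test) and at -8.87 points in mRNAs of Polycomb, SET1 and HUSH subunits (adjusted p = 0.182, exact permutation test). NONO in HepG2 had windows in 4 of 4 nuclear lncRNA genes, as did PPP1R10, EIF4E, SNRPC and PRPF39 (experiments 4114 and 4149) in HepG2.

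Marker genes followed the cell line labels. K562 markers, among them globin and erythroid factor genes, stood 20.6 points ± 16.3 (SD, n = 45) above all genes in K562 experiments and at -13.8 points ± 13.1 (n = 21) in HepG2 experiments (adjusted p = 2.5e-14, exact permutation test). HepG2 markers such as albumin and apolipoprotein genes stood at -20.5 points ± 19.3 in K562 and 27.1 points ± 28.1 in HepG2 (adjusted p = 6.3e-10, exact permutation test). Of the markers of fibroblasts, lymphocytes and endothelium only 3 genes had a window in any experiment, and that list was at -7.39 points ± 13.7 in K562 and -16.2 points ± 13.6 in HepG2 (adjusted p = 0.0278, exact permutation test). A list meant for neither line thus also differed between them. The marker tests took experiments as independent, although 14 proteins were studied in both lines and DEK and PRPF39 were repeated in HepG2.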

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

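In the 7 classes with 4 to 9 proteins, no protein stood apart from its class by Dixon's ratio at the 95% level. The gaps nearest to the critical values were those of FUBP1 among the intronic regulators (ratio 0.651, critical value 0.710) and of AGO2 among the 3' UTR regulators (ratio 0.549, critical value 0.829).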

How the results depend on the processing

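The alternatives named in processing as added after seeing the data are those without windows listed in 15 or more experiments, without windows of the shared sets, without PRPF39 K562 and DEK 4146, with splice-site adjacent windows only and with 1 nt of overlap. For the replicate numbers, no paired analysis was possible because the deposited tables join the replicates, which also left no replicate to leave out. Motif tests were not run. Of 32 main results, 20 kept their direction and side of the threshold under all alternatives run for them, and 265 of 291 alternative values did. The windows per experiment and the DEK and PRPF39 repeats have no threshold. For these, kept meant a value within a fixed fold change, or within the main Wilson interval for the repeats. A result that missed the threshold counted as kept where it missed it again in the same direction. The FXR result ranged from 45.4 to 72.5 points, the overlap between lines from a percentile of 84.7 to 93.2, and the class overlap from 0.247 to 2.18, each past the threshold throughout. Of 225 values of 45 named genes, 215 kept their sign. The causes of the changes below were not tested, except that a stricter q lists fewer windows.

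With a highest q of at most 0.01, the median list fell to 711 windows. The spliceosomal difference was 6.24 points (adjusted p = 0.0546, exact permutation test), the 3' UTR difference 27.3 (adjusted p = 0.0519, exact permutation test), and 13 proteins bound their own gene (p = 0.133, permutation test). The shared share of the repeats was 34.4% for DEK and 72.1% for PRPF39. The snRNA list passed at 16.1 points (adjusted p = 0.0192, exact permutation test), and the microRNA host genes turned to 12.6. The named genes that turned sign were TCAF1P1 and CCDC85B (-2.22 points each), MIR6803 (-4.44), MEIOB (-17.8), TRAF4 (-22.2), FRMD4B (-7.67), NSMF (-12.2), CAPN10 (-4.55) and PCYOX1 (-6.82).

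Without windows listed in 15 or more experiments, the 3' UTR difference was 15.4 points (adjusted p = 0.0579, exact permutation test), the DEK repeats shared 43.9%, and the mitochondrial list and MT-ND3 turned to -4.67 and -23.9 points. Without windows of the shared sets, the 3' UTR difference was 15.7 points (adjusted p = 0.0632, exact permutation test). Without PRPF39 K562 and DEK 4146, the 7SK and 7SL list passed at 36.2 points (adjusted p = 0.0219, exact permutation test). With genes counted once per feature, the spliceosomal difference was 5.60 and the 3' UTR difference 10.7 points (adjusted p = 0.0913 and 0.0746, exact permutation tests). A minimum of 200 windows gave 15.3 points for 3' UTRs (adjusted p = 0.0544, exact permutation test), and K562 alone 5.35 points for the spliceosome (adjusted p = 0.209, exact permutation test). Counted by genes, the repeats shared 70.4% (DEK) and 87.0% (PRPF39). As a log odds ratio, the snRNA list passed at 3.36 (adjusted p = 0.00176, exact permutation test) and the mitochondrial list turned to -0.0717. Leaving out 1 protein at a time gave -3.57 (without SRSF1) to 28.4 points for SR proteins, 8.70 (without AGO2) to 22.4 (without CNOT2) for 3' UTRs, and 16.2 to 35.2 (without FUBP1) for intronic regulators. Over its alternatives the adjusted p of the 3' UTR result ranged from 0.00358 to 0.182 (exact permutation tests), and that of the spliceosomal result from 7.0e-07 to 0.209 (exact permutation tests).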

Other observations

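All tests of the shared sets of windows, the test for a wrong label of DEK 4146 and the test of often listed windows for PRPF39 were chosen after the result was seen, as were the pairs of proteins and the windows of the sets named here. Some lists shared many windows with those of proteins outside their own class. In K562, DDX1, a DEAD-box protein, and NONO shared 9237 windows, 50.9% of the NONO list (log2 odds ratio of overlap, 5.76). DDX43 (experiment 4160) and the exosome subunit EXOSC10 (experiment 4161) shared 8960 windows, 93.4% of the EXOSC10 list (6.89). SRSF1 and EXOSC10 shared 8084 (5.74). All 3 proteins had mainly coding windows, and whether that accounts for the overlap was not tested. RYBP and METTL1, a tRNA methyltransferase, shared 3649 windows, 41.9% of the RYBP list.

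SF3A1 in HepG2 had windows in 61 of 226 microRNA genes, the second most after AGO2, and in 17.2% of all named genes. In the authors' deposited table its highest windows lay in MIR17HG, in NFYC and at the MIR25, MIR93 and MIR106B genes within MCM7, with log2 odds ratios of 12.37, 11.75 and 11.66. NFYC also held the highest AGO2 window. The MIR17HG window was listed in 17 experiments. ELAVL1 and TIAL1 had the lowest median G+C content of their windows, 35.2% and 36.0%, and EIF4E the highest, 66.1%.

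The highest windows of many experiments were the same for different proteins. Joined by the experiments that list them, the windows that stood among the 10 highest of at least 3 proteins formed 6 sets, 4 of them with a median of at most 2 input reads. Set 6, with PRTFDC1 (chromosome 10, 24889234 to 24889333) and MYO9B (chromosome 19, 17082471 to 17082570), was listed in 12 K562 experiments from FMRP to EIF3A, ELAC2 and RYBP. Set 2, with FBXW8, CARMIL1 and DMD, was found in 10 HepG2 and 3 K562 experiments. Set 3, with SPIN4, PRKCA and AGAP1, was found in 6 HepG2 experiments and 1 K562 experiment. They cover 5 proteins of 2 classes (spliceosomal and chromatin), since the repeats of DEK and of PRPF39 are among them. Set 1, led by BTBD2, was found in 6 K562 and 3 HepG2 experiments and made up 26.3% of the 38 windows of PARP. A leading window of these sets was the highest window of 29 of their 41 experiments.

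None of the explanations tested for these sets was excluded. A high abundance of the RNA in 1 line stays open: at most 45.5% of a line's experiments listed the same one of the 4 sets, against up to 73.3% for the other 2, but choosing sets for few input reads leaves out abundant RNAs beforehand. A shared function could not be told apart from chance, because 13.1% of the 199 pairs of different proteins within 1 of the 4 sets belonged to 1 class, against 9.81% with permuted classes (p = 0.0909, permutation test). A feature of the library, such as its adaptor, was not decided either. 0 experiments belonged to more than 1 of the 4 sets. Windows were joined by the experiments that list them, which keeps the sets apart by construction. The adaptor of each library was not analysed here. Some members had consecutive experiment numbers, as HepG2 4081 to 4084 and 4202 to 4204 in set 2 and K562 4222 to 4225 in set 6. Others broke such runs, as K562 4139 in set 1 lies between 4138 and 4140 of set 6. What the numbers stand for is not given in the sources used here, and their relation to the sets was not tested.

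Experiments of 1 protein listed different windows for DEK in HepG2 (62.3% against 13.2% coding) and for PRPF39, whose K562 list had 52.3% small RNA exons and shared 97 of 172 windows with NPM1. List length was argued against as the whole cause: the 1046 strongest DEK 4020 windows were 40.4% coding, above the interval of 4146, though the gap of 49.2 points fell to 27.2, and the strongest PRPF39 windows in HepG2 held at most 4.65% small RNA exons, below the K562 interval of 44.9% to 59.7%. Often listed windows were argued against too, as the DEK gap was 50.6 points without them and they made up 1.16% of the PRPF39 K562 list, and so were shifted window borders, with 0% of the K562 windows touching a HepG2 window. A wrong label of DEK 4146 may remain, since 4 of 20 HepG2 experiments of other proteins overlapped with it more than DEK 4020 did. These were DHX38 (98 windows), PARP (38), SNRPA1 (516) and SNRPD3 (706), against 4236 windows of DEK 4020. Short lists had high odds ratios with most others, so this count does not decide the question. The highest Jaccard index of DEK 4146 with another protein was 0.273, against 0.103 with DEK 4020. That index does not count against a wrong label, because even the PRPF39 repeats reached only 0.325. A wrong label of the PRPF39 K562 experiment was not tested and stays open. It ranked 45 of 45 K562 experiments by overlap with each HepG2 PRPF39 experiment, and its log2 odds ratio with NPM1 was 9.89. For PRPF39 the cell line is an untested biological explanation, and with 1 K562 experiment it cannot be separated from that experiment.

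ELAC2, the tRNA 3' end endonuclease, listed 81.3% of the TDP43 windows in K562. The length of the ELAC2 list, 59643 windows, could not be excluded: it held 80.9% of the intronic TDP43 windows, above the median of 17.6% over 37 other experiments without NONO (65.8%) but below the 85.7% of MORC2. Material of TDP43 carried into the ELAC2 libraries is consistent with the strength of the shared windows, whose median percentile within ELAC2 was 85.7, against a median of 27.1 and at most 62.6 for 38 other experiments. Log2 odds ratios of the 9602 shared windows correlated across windows, which are not independent replicates (Pearson r = 0.467, Spearman rho = 0.410). Binding of both proteins to the same sites stays open: of the windows of TARDBP in HepG2, a separate experiment, ELAC2 in K562 listed 27.0% (log2 odds ratio 2.21, rank 2 among the HepG2 experiments, against 0.87 and rank 15 for NONO), which does not decide between both, and the comparison with the median of the other experiments was added after the value of 85.7 was seen.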
